A study of Mus musculus with 8 samples.

How the data were processed

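RNA from 8 pools of 2-cell mouse embryos was measured on Affymetrix gene expression arrays, 1 array per pool. Per the labels' protocols, C57BL/6 females received 5 IU of each gonadotropin before mating, oviducts were flushed 46 to 48 hours after hCG, about 26 embryos were pooled, and RNA was amplified and labelled with biotin. The groups follow the genotype of the sire in the labels: 3 arrays C57BL/6, 3 KDM1A TG and 2 nonTG. The deposited values are log2 expression summaries per probeset, and the submitters' processing notes name R 3.1.0, oligo, RMA and limma without giving the role of each. Background correction, annotation and any filter on probesets are not given in the sources used here. The array columns do not share a common distribution over the probesets held here, so values were used as deposited and other scalings were tried as alternatives. All 8 columns were used. Scanner files were not used here, so no value can be called above or below background, and the filter below stands in for it.

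Of 22961 probesets, 15745 carried 1 gene symbol, 1320 several and 5896 were unnamed here. Gene names came from the platform annotation, and 15621 of the named probesets were found by gene identifier in NCBI RefSeq genes of GRCm38.p6, used for names only. Probesets with several symbols or none entered the filter and 1 alternative, and no gene was named from them. Each gene was represented by its brightest probeset over all arrays, which mattered for 574 genes with several. Of 14995 genes, 11444 had a mean above the 30th percentile of all probesets (log2 2.07) and were tested. Kdm1a had no probeset carrying that symbol alone and was not analysed here.

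Group means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 8 arrays, which share 1 estimate of the spread, and contrasts were tested two-sided with Benjamini-Hochberg adjustment over genes at 0.05. For both kinds of sires together, the 5 arrays formed 1 group against 3. Intervals are 95%. Where the mean of a group lay under the filter level, the fold of a gene that passed is given as at least the ratio of the brighter mean to that level, and its log2 change is as measured. Such a bound is taken from group means without their error, so it is not a confidence limit. The tests, groups, filter, thresholds, gene lists and the rule for named genes were chosen before the data were examined. The rule takes, per comparison, the 10 largest rises and falls among genes that passed with arrays that did not overlap, filled with the smallest p on that side, leaving out predicted genes, small RNA families, olfactory and vomeronasal receptors and antigen receptor segments, and up to 4 members of each list by smallest p. Of the genes that passed, 7, 4, 1 and 19 in the 4 comparisons, in the order reported, carried such symbols.

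Of 28 gene lists written, 27 had at least 5 genes tested. They cover the 2-cell stage (2-cell activation, maternal oocyte genes), lineage genes, chromatin, growth and metabolism, and cells that a flushed embryo pool could hold (oviduct epithelium, stroma and muscle, cumulus and granulosa cells, blood, sperm). Lists were tested with camera of limma at a preset correlation of 0.01 and adjusted over lists. No list call held with an estimated correlation in any comparison, and fry called 2 lists in 1 comparison. Fry tests whether the genes of a list move one way on balance, and does not compare them with other genes. Changes of lists are given relative to the median change of all genes because other scalings moved that median, for KDM1A TG against C57BL/6 from 0.18 to values between 0.07 and 0.25.

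Alternatives covered the filter, scaling (quantile, cyclic loess, median centring), variance model, array weights, arrays in the fit, replicate number as a block, probeset choice, thresholds, set tests and leaving out each array. The oviduct marker mean as a covariate and leaving out the 2 arrays with the widest values were chosen after seeing the data. On data simulated with 200 changed genes among 11444, the KDM1A TG against C57BL/6 test recovered 33% of 2-fold and 99.4% of 4-fold changes with 6 false calls on average over 10 runs, and the nonTG against C57BL/6 test 21.5% and 97.4% with 4.4. The test of both together recovered 49.2% and 100%, with 7.7 false calls. In these and the simulations below genes were drawn independently, without the correlation between genes that the arrays hold. The rates and ranges may therefore not carry over to these data. Chance agreement between comparisons with shared controls was simulated 100 times for all arrays and 100 times without each array. The overlap of called genes was set against 100 such simulations, taking as many genes by smallest p on each side as were called, and these last 2 sets of simulations were chosen after the data were seen.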

Results

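RNA was measured in pools of 2-cell mouse embryos whose fathers differed. C57BL/6 females were superovulated and mated with C57BL/6 males, with males carrying a KDM1A transgene (KDM1A TG), or with the non-transgenic littermates of those males (nonTG). KDM1A, also called LSD1, removes methyl groups from histone H3 lysine 4. Embryos are named here after their sire, and the genotype of the embryos themselves was not determined. Embryos were flushed from the oviducts 46 to 48 hours after hCG, and each pool held 26 embryos on average. The series concerns disturbed histone methylation in developing sperm, and this part asks how the RNA of 2-cell embryos differs with the kind of sire. The 8 arrays comprised 3 pools sired by C57BL/6 males, 3 by KDM1A TG males and 2 by nonTG males, and this number limits the precision of every value. The labels do not say whether the pools of a group came from different males, so the p-values measure only the spread between these pools, which may be technical.

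The deposited log2 values ran from 0.12 to 12.36, with medians of 2.73 to 2.86 per array. Pairs of arrays correlated at 0.889 to 0.967 across probesets. The interquartile range was 2.38 in KDM1A TG replicate 1 and 2.604 in KDM1A TG replicate 3, against 1.87 to 2.09 in the other 6 arrays. Kdm1a itself had 0 probesets carrying its symbol alone and was not analysed here, so the labels were not checked against it. The median log2 change of all 11444 genes was 0.18 for KDM1A TG against C57BL/6, 0.04 for nonTG against C57BL/6 and 0.16 for KDM1A TG against nonTG, and 0.09, 0.06 and 0.05 after quantile normalization. The medians of gene lists are therefore given relative to the median of all genes.

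Embryos of KDM1A TG sires were compared with those of C57BL/6 sires to find what distinguishes offspring of transgenic males from those of the control strain (n = 3 and 3). Car3, a carbonic anhydrase abundant in muscle and fat, rose most, by 5.79-fold (95% interval 3.58 to 9.39, log2 change 2.53, SE 0.35, adjusted p = 3.1e-06). Its log2 values were 7.08, 5.93 and 6.2 in the KDM1A TG arrays and 4.05, 3.33 and 4.23 in the C57BL/6 arrays. Jam2, a junctional adhesion molecule, rose 3.91-fold (SE 0.33 on the log2 scale, adjusted p = 0.000207), and Myd88, the adaptor of Toll-like receptors, rose 3.85-fold (SE 0.36, adjusted p = 0.000961). Fabp4, a fatty acid binding protein of adipocytes and macrophages, rose 3.69-fold (SE 0.36, adjusted p = 0.00222). Acta2, the actin of smooth muscle, rose 3.38-fold (SE 0.40, adjusted p = 0.0155). Without C57BL/6 replicate 3 the log2 change of Fabp4 was 1.22 (adjusted p = 0.143), and without KDM1A TG replicate 3 that of Acta2 was 1.05 (adjusted p = 0.8).

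Fxyd4, a regulator of the sodium pump, rose 3.85-fold, Fads2b, a fatty acid desaturase family member, 3.30-fold, and Kctd12, an auxiliary subunit of GABA-B receptors, 3.25-fold (adjusted p = 0.00135, 0.00834 and 0.00348), though Fads2b did not pass without KDM1A TG replicate 3 (adjusted p = 0.733). Second probesets gave smaller changes from C57BL/6, of 0.98 in KDM1A TG and 0.79 in nonTG for Kctd12 (1.70 and 1.74 for the one used). For Atp5d they were 0.71 and 0.78 (1.43 and 1.05), and for Alyref2 -0.76 and -0.83 (-0.93 and -1.55). The U3 small nucleolar RNA gene Rnu3a rose 3.88-fold and the pseudogene Rps19-ps3 rose 3.28-fold (adjusted p = 0.000326 and 0.00431). Probesets of such genes can also bind copies elsewhere in the genome. Among members of the fixed lists, the p53 targets Ccng1 (log2 change 1.68) and Btg2 (1.54), the sodium pump subunit Atp1b1 (1.40), the ATP synthase subunit Atp5d (1.43), the homeobox gene Hoxb8 (1.31) and the Notch target Hey2 (1.33) rose, with adjusted p between 0.00297 and 0.0383. Pilrb1, a paired immunoglobulin-like receptor, fell by 1.26 on the log2 scale (SE 0.33, adjusted p = 0.0405), to a mean of 1.65 under the filter level of 2.07, and was at least 1.8-fold lower. S100a9, a calcium-binding protein of neutrophils, fell by 1.92 (SE 0.42, adjusted p = 0.0111), with arrays that overlapped between the groups. It stood at 6.41 in C57BL/6 replicate 1 and at 2.82 and 3.70 in the other C57BL/6 arrays, and without that replicate its change was -0.87 and did not pass (adjusted p = 0.526). The 9 genes with the next smallest p on the lower side and arrays that did not overlap did not pass, among them Lce1h (log2 change -1.18, adjusted p = 0.0526), the ribosome biogenesis factor Nop56 (-1.07, adjusted p = 0.0959) and the mitotic kinase Aurkb (-1.01, adjusted p = 0.147).

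In all, 83 of 11444 genes passed limma's test, 75 higher and 8 lower in KDM1A TG, and 1620 did so at an unadjusted p under 0.05. The 2 groups' arrays did not overlap for 19.8% of genes, where chance gives 10%. After quantile normalization 5 genes passed, 4 higher (Car3, Jam2, Rnu3a and Snord15a) and 1 lower (Mir365-1), and cyclic loess also gave 4 higher and 1 lower. Only Mir365-1 passed with the oviduct marker mean as a covariate. Without KDM1A TG replicates 1 and 3, which left 1 KDM1A TG array, its log2 change was -2.8. Leaving out single arrays gave 9 genes without KDM1A TG replicate 3, 228 without KDM1A TG replicate 2, and 33, 254 and 30 without C57BL/6 replicates 1, 2 and 3. Mir365-1 and Snord15a were outside the naming rule and were chosen after their values were seen.

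**Figure D1:**
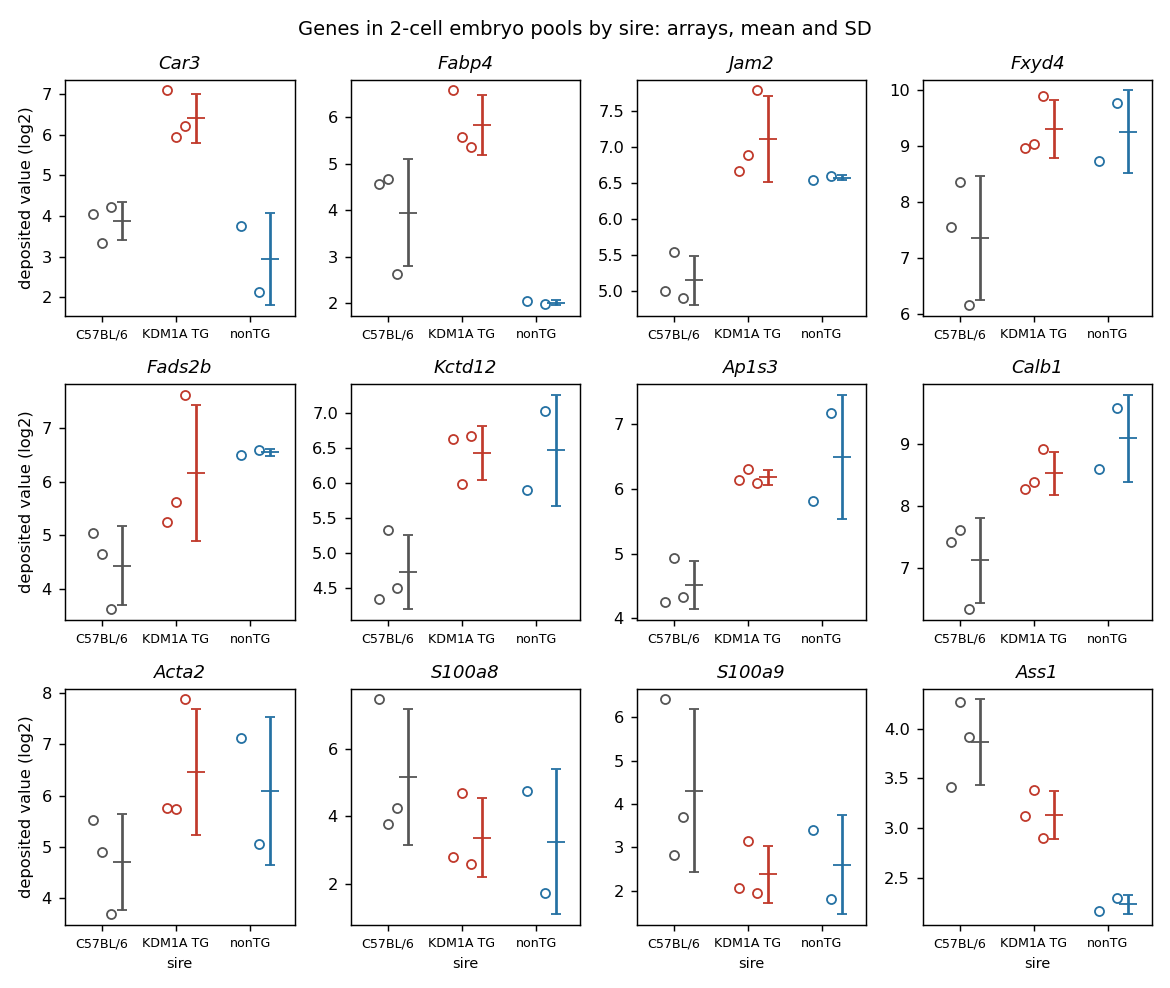
Deposited log2 values (vertical axes) of 12 genes in each array (circles) by sire (horizontal axes), with group means and SD (bars, n = 3 C57BL/6, 3 KDM1A TG and 2 nonTG). Car3 lay between 5.93 and 7.08 in the KDM1A TG arrays and between 2.14 and 4.23 in the other arrays, while Fxyd4 was at a mean of 9.31 in KDM1A TG and 9.26 in nonTG against 7.36 in C57BL/6.

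Of the 27 gene lists tested, 7 were higher and 3 lower in KDM1A TG than in C57BL/6 embryos by camera with a preset correlation, and 5 lists passed without C57BL/6 replicate 3. Nuclear-encoded oxidative phosphorylation genes, mostly subunits of the respiratory chain and ATP synthase, stood 0.34 above all genes on the log2 scale (adjusted p = 6.68e-06, and adjusted p = 0.708 with an estimated correlation). Assembly factors of complex I such as Ndufaf1 are also in the list, and 69 of its 73 genes had a change above 0. After quantile normalization their median was 0.20 and after cyclic loess 0.15. Atp5d passed over all genes, and 2 members passed adjusted over the list alone. Sdha of complex II had a log2 change of 1.16 and Uqcrc2 of complex III one of 1.01, short of the threshold over all genes. Stromal and muscle cell markers stood 0.69 above all genes, with all 18 members above 0 (adjusted p = 1.17e-05, and adjusted p = 0.708 with an estimated correlation). Their mean level was 5.651 in KDM1A TG replicate 3 and 4.467 and 4.242 in replicates 1 and 2, against 4.075, 4.347 and 3.557 in the C57BL/6 arrays. Acta2 passed over all genes and 9 members passed adjusted over the list alone, and Tagln, Mgp and Cnn1 had log2 changes of 1.25, 1.30 and 1.25.

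Spliceosome genes (0.28 above all genes, 46 of 48 above 0), heat shock and unfolded protein response genes (0.38, 28 of 30), proteasome genes (0.31, 34 of 36) and lipid and cholesterol metabolism genes (0.22, 30 of 36) also shifted up (adjusted p = 0.00114, 0.00125, 0.00125 and 0.00719, and adjusted p = 0.708 for each with an estimated correlation). After quantile normalization these 4 medians were 0.10, 0.24, 0.16 and 0.13, and spliceosome and proteasome genes did not pass (adjusted p = 0.134 and 0.074). After cyclic loess they were 0.06, 0.20, 0.08 and 0.13, and spliceosome, heat shock and proteasome genes did not pass (adjusted p = 0.46, 0.078 and 0.27). No member of these 4 lists passed over all genes, and 6 lipid genes passed adjusted over the list alone. Among them, Prpf8 (log2 change 0.97), Hsp90b1 (0.81), Pomp (0.90) and the fatty acid synthase gene Fasn (1.17) had some of the smallest p. Fry's directional test placed spliceosome genes (adjusted p = 0.00998) and preimplantation lineage and pluripotency genes (adjusted p = 0.0183) on the higher side. The lineage list, with Atp1b1, Id2 (log2 change 1.17) and Krt8 (1.06), did not pass camera (adjusted p = 0.117), and its median stood at -0.02 relative to all genes.

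Oviduct epithelial cell markers moved with these lists and stood 0.36 above all genes, with 19 of 20 above 0 (adjusted p = 0.00191, and adjusted p = 0.708 with an estimated correlation). Their mean level was 5.42 ± 0.31 (SD, n = 3) in C57BL/6 and 5.95 ± 0.44 (SD, n = 3) in KDM1A TG embryos, with 6.17, 5.45 and 6.25 in KDM1A TG replicates 1, 2 and 3. The oviduct list did not pass after quantile normalization (0.20, adjusted p = 0.0558) or cyclic loess (0.19, adjusted p = 0.244). Maternal oocyte genes, transcripts loaded into the egg, stood 0.35 lower than all genes (relative median -0.35, 36 of 52 with a change below 0, adjusted p = 0.00125, and adjusted p = 0.729 with an estimated correlation). Genes of 2-cell activation, transcribed as the embryonic genome starts, had a relative median of -0.21 and cumulus and granulosa cell markers one of -0.43 (adjusted p = 0.025 and 0.0495, and adjusted p = 0.729 and 0.708 with an estimated correlation). The 2-cell median was -0.37 after quantile normalization and -0.39 after cyclic loess, and the cumulus list did not pass after either (-0.22 and -0.20, adjusted p = 0.155 and 0.27). Leaving out KDM1A TG replicates 1 and 3 left 1 KDM1A TG array, whose spread was taken from the other groups, so only medians are given. The oviduct median was then -0.03, and the maternal and 2-cell medians turned to 0.23 and 0.29. Spliceosome genes stood at 0.30 and stromal markers at 0.20. Oxidative phosphorylation, heat shock, proteasome and lipid genes stood at 0.12, 0.05, 0.15 and 0.16. With the oviduct marker mean as a covariate the maternal and 2-cell medians turned to 0.32 and 0.34, both then higher by camera (adjusted p = 0.000922 and 0.00232, and adjusted p = 0.495 and 0.48 with an estimated correlation), and the stromal median to -0.11. Under this covariate oxidative phosphorylation, heat shock, proteasome and lipid genes had medians of 0.05, 0.09, 0.10 and 0.12 and did not pass (adjusted p = 0.496, 0.199, 0.199 and 0.118), nor did stromal and cumulus markers (adjusted p = 0.721 and 0.105). Spliceosome genes stood at 0.32 (adjusted p = 0.000272, and adjusted p = 0.48 with an estimated correlation). Of lists not called without it, ribosome biogenesis (0.41), cell cycle (0.34), RNA polymerase II (0.27), histone (0.50), DNA repair (0.22) and lineage genes (0.24) then passed as higher (adjusted p = 4.79e-05, 0.000172, 0.000922, 0.00149, 0.0465 and 0.0465, and adjusted p = 0.48 for each with an estimated correlation). Blood and immune markers passed as lower (-0.50, adjusted p = 0.00284, and adjusted p = 0.48 with an estimated correlation). In the fit without the covariate, histone lysine demethylases, histone H3K4 methyltransferase subunits and KDM1A complex partners did not pass (adjusted p = 0.92, 0.813 and 0.34). These lists hold the genes closest to the transgene's function. The demethylases' test leaned lower than other genes in that fit. Their mean log2 change of 0.14 lay below the median of 0.18 for all genes, and their median stood 0.07 above it.

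Embryos of nonTG sires, whose fathers shared the litters of the transgenic males and lacked the transgene, were compared with C57BL/6 embryos in the same way (n = 2 and 3). Fads2b rose 4.30-fold (95% interval 2.42 to 7.63, log2 SE 0.42, adjusted p = 0.00768). Ap1s3, a subunit of a clathrin adaptor complex, rose 3.96-fold (SE 0.37, adjusted p = 0.00578), and Calb1, the calcium buffer calbindin, 3.92-fold (SE 0.38, adjusted p = 0.00639). Fxyd4, the sulfotransferase gene Sult1d1, Kctd12, the mitochondrial carbonic anhydrase gene Car5b and the aldo-keto reductase gene Akr1e1 rose by 1.63 to 1.90 on the log2 scale (adjusted p = 0.0122 to 0.0412). Fabp4 fell by 1.94 on the log2 scale (SE 0.41, adjusted p = 0.013), to a mean of 2.01 ± 0.05 (SD, n = 2) from 3.95 ± 1.15 (SD, n = 3), and was at least 3.68-fold lower, the nonTG mean being under the filter level of 2.07. Ass1, an enzyme of the urea cycle, fell by 1.63 (SE 0.36, adjusted p = 0.0232), and Krtap4-13, a keratin-associated protein gene, fell by 1.75 (SE 0.39, adjusted p = 0.0232). Without nonTG replicate 2 the log2 changes of Ap1s3, Car5b and Krtap4-13 were 1.31, 0.82 and -0.68 and did not pass (adjusted p = 0.457, 0.804 and 0.83), and without nonTG replicate 1 those of Car5b and Krtap4-13 were 2.62 and -2.83. Alyref2, an mRNA export factor, had a log2 change of -1.55 that did not pass (adjusted p = 0.0521).

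In total 15 genes passed, 8 higher and 7 lower in nonTG, and 941 did so at an unadjusted p under 0.05. Arrays of the groups did not overlap for 24.8% of genes, where chance gives 20%. Of the 7 lower genes, Mir365-1, Mir101c, Gm5166 and Gm26504 were outside the naming rule and are named after their values were seen. Quantile normalization and cyclic loess each left 1 gene, the lower Mir365-1, and 4 lower genes (Mir365-1, Gm5166, Retnla and Dcpp2) passed with the oviduct marker mean as a covariate. Without C57BL/6 replicate 2, 80 genes passed, without nonTG replicate 1, 51, without nonTG replicate 2, 3, without KDM1A TG replicate 1, 31, and without KDM1A TG replicate 2, 4.

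Gene lists shifted both ways between nonTG and C57BL/6 embryos, with 6 higher and 5 lower of 27. Maternal oocyte genes shifted most, with a median of -0.65 relative to all genes and 46 of 52 members below 0 (adjusted p = 5.2e-12, and adjusted p = 0.673 with an estimated correlation). None of them passed singly, and the log2 changes were -1.30 for Fbxw15, -1.05 for the nucleoplasmin gene Npm2 and -1.11 for Dppa3, a protector of maternal DNA methylation. Genes of 2-cell activation (relative median -0.46, 32 of 43 below 0), cell cycle genes (-0.38, 40 of 51), ribosome biogenesis genes (-0.31, 30 of 40) and replication-dependent histone genes (-0.25, 11 of 14) were also lower (adjusted p = 9.23e-06, 0.00034, 0.00981 and 0.0287, and adjusted p = 0.673 for each with an estimated correlation). Usp17lc, Pramel6 and the proliferation marker gene Mki67 had log2 changes of -1.18, -1.15 and -1.03 without passing.

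Oxidative phosphorylation genes (relative median 0.45, 63 of 73 above 0), heat shock genes (0.38, 26 of 30), proteasome genes (0.23, 31 of 36) and spliceosome genes (0.16, 35 of 48) were higher in nonTG (adjusted p = 1.68e-07, 0.00386, 0.0273 and 0.0287, and adjusted p = 0.673 for each with an estimated correlation). After cyclic loess these 4 medians were 0.23, 0.26, 0.10 and 0.02, and heat shock, proteasome and spliceosome genes did not pass (adjusted p = 0.0632, 0.315 and 0.498). Proteasome and spliceosome genes did not pass after quantile normalization either (0.17 and 0.11, adjusted p = 0.0998 and 0.173). The oviduct epithelial cell markers were higher in the same arrays (0.48, 20 of 20), as were the stromal and muscle cell markers (0.47, 16 of 18, adjusted p = 9.23e-06 and 0.000595, and adjusted p = 0.673 for each with an estimated correlation). The oviduct marker mean was 5.97 ± 0.15 (SD, n = 2) in nonTG, and the maternal gene mean was 4.43 ± 0.34 (SD, n = 2) against 4.96 ± 0.37 (SD, n = 3) in C57BL/6. With the oviduct marker mean as a covariate none of the called lists passed (adjusted p of 0.0646 or more), the oviduct markers themselves not being tested. The 1 list that then passed was blood and immune cell markers, lower by 0.54 relative to all genes (relative median -0.54, adjusted p = 0.000108, and adjusted p = 0.894 with an estimated correlation). The maternal median was -0.04, the 2-cell median 0.06, the cell cycle median 0.22 and the oxidative phosphorylation median 0.08. Without nonTG replicate 1, 4 lists passed, without C57BL/6 replicate 3, 7, and the stromal median without nonTG replicate 1 was -0.06.

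**Figure D2:**
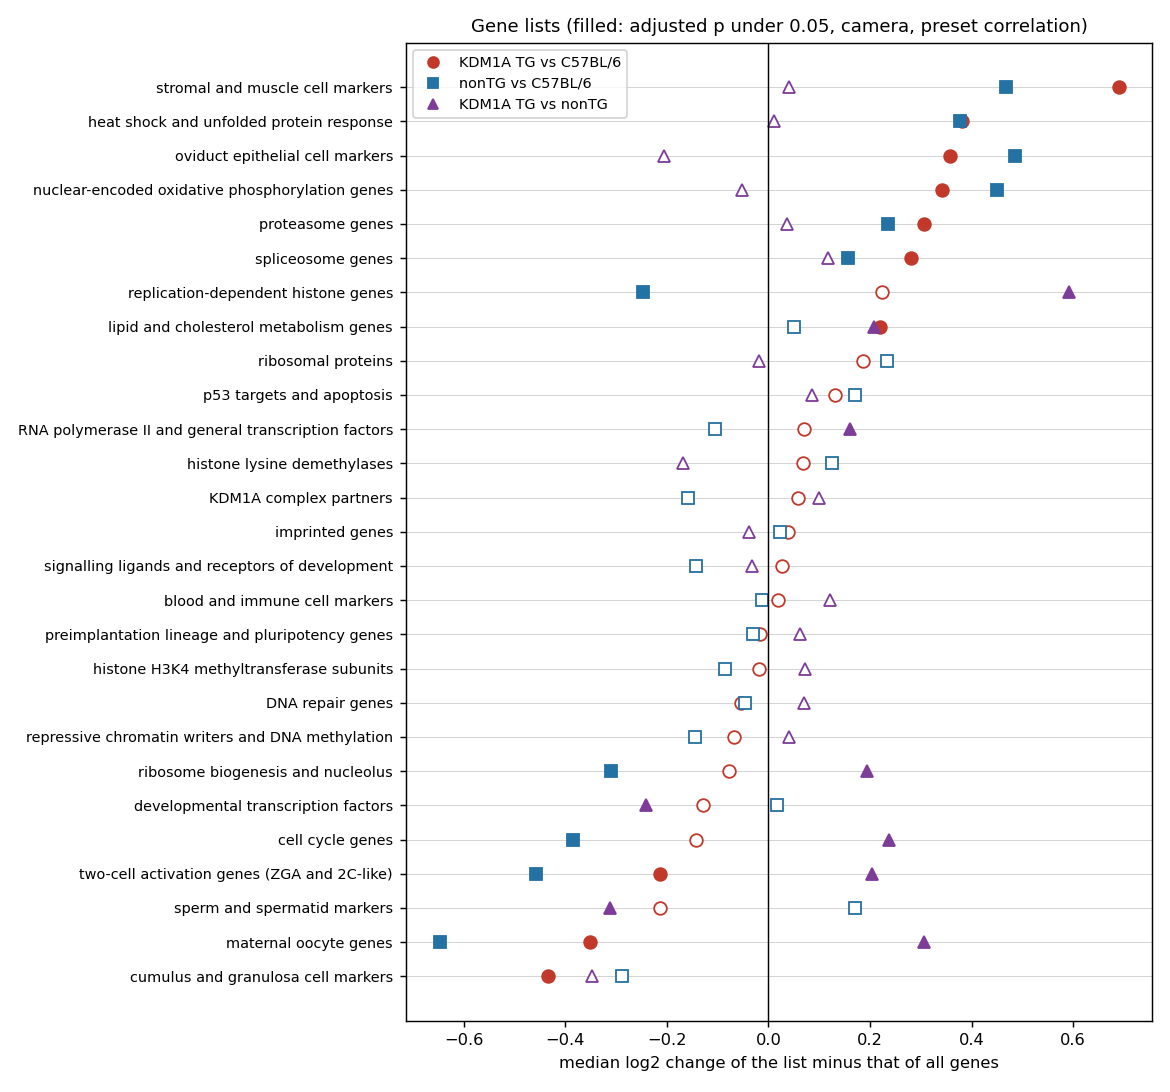
Median log2 change of each of 27 gene lists minus that of all genes (horizontal axis, log2) for 3 comparisons of sires (marker shapes), with filled markers at an adjusted p under 0.05 by camera. Maternal oocyte genes lay at -0.35 for KDM1A TG against C57BL/6, -0.65 for nonTG against C57BL/6 and 0.31 for KDM1A TG against nonTG.

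The direct comparison of KDM1A TG with nonTG embryos asks what goes with the transgene among sires of 1 line (n = 3 and 2). By its group means Fabp4 was at least 13.6-fold higher in KDM1A TG (measured log2 change 3.82, SE 0.41, adjusted p = 1.76e-10). Its nonTG mean of 2.01 lay under the filter level of 2.07, and the bound leaves out the error of the means. Car3 rose 11-fold (95% interval 6.41 to 18.9, log2 change 3.46, SE 0.39, adjusted p = 1.26e-09). All 3 KDM1A TG arrays lay above both nonTG arrays for each gene, and both passed under each of the 20 alternatives run for single genes, with adjusted p of at most 0.00231 and 0.012. A second Car3 probeset gave log2 changes of 1.71 in KDM1A TG and -0.67 in nonTG against C57BL/6. H2bc12, a histone H2B gene, rose 3.41-fold (SE 0.39, adjusted p = 0.0494), and Isoc2a, an isochorismatase domain gene, was at least 2.12-fold higher (measured log2 change 1.67, SE 0.37, adjusted p = 0.0494), with a nonTG mean of 1.48 under that level. Gm17695, a predicted gene outside the naming rule and named after its values were seen, fell by 1.85 as measured (SE 0.37, adjusted p = 0.0105) and was at least 2.71-fold lower, with a KDM1A TG mean of 1.65.

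These 5 genes, 4 higher and 1 lower, were those that passed, against 733 at an unadjusted p under 0.05, and the arrays did not overlap for 22.4% of genes, where chance gives 20%. Quantile normalization and cyclic loess left Fabp4 and Car3, 2 higher genes and no lower gene. H2bc12 and Isoc2a had adjusted p of 0.00615 to 0.9995 and 0.00402 to 0.642 over their alternatives, and neither passed after these scalings, with the oviduct covariate or without nonTG replicate 1. Single arrays moved the count to 8 without KDM1A TG replicate 1, 2 without KDM1A TG replicate 2 or 3, 17 without nonTG replicate 1 and 11 without nonTG replicate 2.

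The list of replication-dependent histone genes had the largest shift, 0.59 above all genes with 11 of 14 above 0 (adjusted p = 0.000177, and adjusted p = 0.505 with an estimated correlation). Its members were picked by symbol, so not all need be replication-dependent, and H1f8 also belongs to the maternal oocyte list. H2bc12 passed over all genes and 6 members adjusted over the list alone, and H2bc1 and the linker histone gene H1f5 had log2 changes of 1.52 and 1.55. Maternal oocyte genes stood 0.31 above all genes, 45 of 52 members above 0 (adjusted p = 0.000177, and adjusted p = 0.84 with an estimated correlation). Ribosome biogenesis genes (0.19, with Nop16 at a log2 change of 1.32), cell cycle genes (0.24), RNA polymerase II and general transcription factor genes (0.16), lipid and cholesterol metabolism genes (0.21, with Scd1 at 1.15) and 2-cell activation genes (0.20) were higher too (adjusted p = 0.00652 to 0.0274, and adjusted p = 0.84 for each with an estimated correlation). Developmental transcription factors (-0.24) and sperm and spermatid markers (-0.31) were lower relative to all genes (adjusted p = 0.0185 and 0.0237, and adjusted p = 0.505 and 0.84 with an estimated correlation). Oviduct markers had a median of -0.21 relative to all genes and did not pass (adjusted p = 0.258). After quantile normalization the histone, maternal and ribosome biogenesis lists kept their calls, with medians of 0.45, 0.27 and 0.19, and the other 6 did not (adjusted p = 0.0736 to 0.216). After cyclic loess the histone and maternal lists alone did (0.47 and 0.27). The 2-cell list did not pass with the oviduct covariate (0.20, adjusted p = 0.0568). Without KDM1A TG replicates 1 and 3, which left 1 KDM1A TG array, the histone, maternal, 2-cell, cell cycle, ribosome biogenesis, RNA polymerase II and sperm medians were 0.97, 0.91, 0.62, 0.60, 0.45, 0.27 and -0.53 (adjusted p of 0.0151 or less, and adjusted p = 0.606 to 0.614 with an estimated correlation). The lipid and developmental factor lists did not pass there (0.07 and -0.19, adjusted p = 0.704 and 0.151). Oxidative phosphorylation genes and oviduct markers newly passed as lower (adjusted p = 0.00214 and 6.82e-05, and adjusted p = 0.76 and 0.606 with an estimated correlation). Of these 9 lists, 1 passed without KDM1A TG replicate 2 and 2 without nonTG replicate 1, where the 2-cell median was -0.22.

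Both kinds of sires from the transgenic line were also set together against C57BL/6 sires (n = 5 and 3). Fxyd4 rose 3.80-fold (95% interval 2.49 to 5.81, log2 SE 0.31, adjusted p = 1.5e-05), Fads2b 3.67-fold (SE 0.31, adjusted p = 2.95e-05), Ap1s3 3.47-fold (SE 0.30, adjusted p = 2.95e-05) and Jam2 3.37-fold (SE 0.30, adjusted p = 4.97e-05). Kctd12, Calb1, Ccng1, the lysosomal protease gene Ctsd, the amino acid transporter gene Slc6a14 and Hdc, which makes histamine, rose between 2.80-fold and 3.28-fold. S100a8 and S100a9, which form calprotectin in neutrophils, fell by 1.84 and 1.83 on the log2 scale (SE 0.35 and 0.33, adjusted p = 0.000367 and 0.000135), and their arrays overlapped between the groups. S100a8 stood at 7.49 in C57BL/6 replicate 1, without which the changes were -0.68 and -0.78 and did not pass (adjusted p = 0.66 and 0.534). The blood and immune list that holds them did not pass (adjusted p = 0.291), and its median log2 change of 0.12 had the opposite sign to its mean of -0.06. Alyref2 fell by 1.17 and Ass1 by 1.09 (SE 0.30 each, adjusted p = 0.0191 and 0.037), and Bambi-ps1, Cyp2a22, Pilrb1 and Magea2 fell by 1.04 to 1.05, with the KDM1A TG means of Bambi-ps1 (1.67) and Pilrb1 (1.65) and the nonTG mean of Bambi-ps1 (1.81) under the filter level. Magea2 was at -0.69 without C57BL/6 replicate 1 and did not pass (adjusted p = 0.642).

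Of 151 genes that passed, 124 were higher and 27 lower, against 1461 at an unadjusted p under 0.05, and arrays of the groups did not overlap for 8.17% of genes, where chance gives 3.57%. Quantile normalization left 5 higher (Ap1s3, Ccng1, Fxyd4, Jam2 and Kctd12) and 1 lower, and cyclic loess and the oviduct covariate left no higher and 1 and 4 lower genes. The count was 34, 232 and 52 without C57BL/6 replicates 1, 2 and 3, 84, 279 and 18 without KDM1A TG replicates 1, 2 and 3, and 71 without nonTG replicate 2.

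Among the lists, 6 were higher and 3 lower in embryos of the line. Oxidative phosphorylation genes stood 0.36 above all genes, with 67 of 73 above 0 (adjusted p = 7.95e-08, and adjusted p = 0.662 with an estimated correlation), and Atp5d and Sdha passed singly with rises of 1.28 and 1.05 on the log2 scale. Stromal and muscle cell markers stood 0.51 above all genes and oviduct markers 0.35 (adjusted p = 7.22e-07 and 4.94e-05, and adjusted p = 0.662 for each with an estimated correlation). Acta2, Cnn1 and Mgp of the former rose by 1.61, 1.18 and 1.12, the last 2 with changes of 0.71 each that did not pass without C57BL/6 replicate 3 (adjusted p = 0.571 and 0.574), and Wfdc2, an abundant secretory epithelial transcript, was the oviduct marker that passed, with a rise of 1.21 (SE 0.30, adjusted p = 0.0124). Heat shock, spliceosome and proteasome genes stood 0.36, 0.24 and 0.29 above all genes (adjusted p = 0.000492, 0.00124 and 0.00154, and adjusted p = 0.662, 0.662 and 0.734 with an estimated correlation). After quantile normalization these medians were 0.23, 0.12 and 0.17 and after cyclic loess 0.19, 0.06 and 0.11, and those of oxidative phosphorylation genes and oviduct markers were 0.17 and 0.19 after cyclic loess. Spliceosome genes did not pass after either scaling (adjusted p = 0.0945 and 0.377), nor did proteasome genes after cyclic loess (adjusted p = 0.233). Maternal oocyte, 2-cell activation and cell cycle genes had relative medians of -0.48, -0.29 and -0.25 (adjusted p = 1.24e-07, 0.000408 and 0.0208, and adjusted p = 0.662, 0.662 and 0.995 with an estimated correlation). With the oviduct covariate these 3 medians were 0.18, 0.25 and 0.30, higher by camera (adjusted p = 0.0341, 0.0141 and 0.0022, and adjusted p = 0.732 for each with an estimated correlation). Oxidative phosphorylation, heat shock, proteasome and stromal lists then had medians of 0.03, 0.12, 0.02 and -0.26 and did not pass (adjusted p = 0.383, 0.218, 0.383 and 0.48), while spliceosome genes stood at 0.27 (adjusted p = 0.000667, and adjusted p = 0.732 with an estimated correlation). Ribosome biogenesis (0.29), RNA polymerase II (0.19) and histone genes (0.23) newly passed as higher and blood and immune markers (-0.53) as lower (adjusted p = 0.000667, 0.0141, 0.048 and 0.000347, and adjusted p = 0.732 for each with an estimated correlation). Without KDM1A TG replicates 1 and 3 the cell cycle list was at -0.18 and did not pass (adjusted p = 0.0597). Blood and immune markers and cumulus markers newly passed as lower (adjusted p = 0.0364 for each, and adjusted p = 0.72 for each with an estimated correlation).

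**Figure D3:**
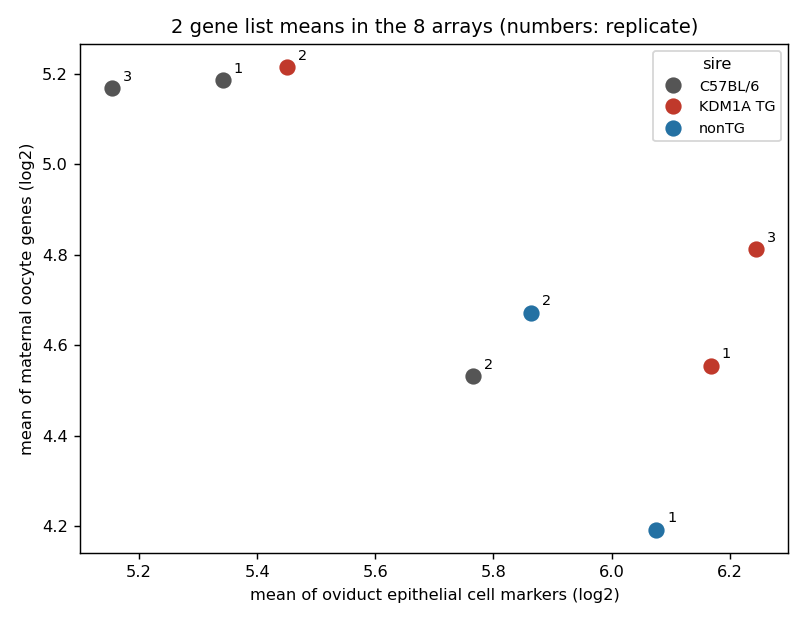
Mean log2 level of 20 oviduct epithelial cell markers (horizontal axis) and of 52 maternal oocyte genes (vertical axis) in the 8 arrays, coloured by sire and numbered by replicate. The 3 arrays with the lowest oviduct means, 5.16 and 5.34 in C57BL/6 and 5.45 in KDM1A TG, had the highest maternal means, 5.17, 5.19 and 5.22.

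The changes of KDM1A TG and of nonTG embryos from the same C57BL/6 arrays were set against each other across genes, which are not independent replicates. They correlated at 0.614 across 11444 genes, where 100 simulations of unchanged groups against shared controls gave 0.447 on average (0.426 to 0.464). The simulated genes were independent of each other, so this and the simulated ranges below may be too narrow. Their covariance was 0.117 against a simulated 0.0543, and the signs matched for 69.8% of genes against 64.8%. Without each array in turn the correlation exceeded that of unchanged groups simulated for the same arrays by 0.0774 (0.625 against 0.547, without C57BL/6 replicate 3) to 0.227 (0.626 against 0.399, without KDM1A TG replicate 2). Ap1s3, Calb1, Fads2b, Fxyd4, Kctd12 and Sult1d1 passed as higher in both comparisons, 6 genes, where as many top genes of unchanged groups simulated with the shared controls had 1.28 in common on average (0 to 4). Mir365-1 passed as lower in both. On the lower side the simulated groups shared 0.26 genes on average (0 to 2), and 24 of 100 simulations shared at least 1. Fabp4 passed in opposite directions. The 3 control arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls, and none of it is taken here as a shared effect.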

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

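The tests of oviduct RNA, of developmental stage and of array spread were chosen only after the results were seen, as were the oviduct covariate, the omission of KDM1A TG replicates 1 and 3, the shares of higher genes in other splits and the bounds on folds, and the limits for array spread in KDM1A TG and for embryo share were narrowed once their values were known. The adipocyte test and the counts of other splits were set beforehand, except for the look at the markers outside the lipid list and at Adipoq, Plin1 and Slc2a4.

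For 5 genes the change from C57BL/6 differed between embryos of KDM1A TG and of nonTG sires, by a test of the difference itself. The difference, KDM1A TG minus nonTG on the log2 scale, was 3.82 for Fabp4 (SE 0.405, adjusted p = 1.76e-10), which stood 1.88 above C57BL/6 in KDM1A TG and changed by -1.94 in nonTG. For Car3 it was 3.46 (SE 0.391, adjusted p = 1.26e-09), with changes of 2.53 and -0.92. H2bc12 differed by 1.77 (SE 0.391, adjusted p = 0.0494), Isoc2a by 1.67 (SE 0.366, adjusted p = 0.0494) and Gm17695 by -1.85 (SE 0.366, adjusted p = 0.0105). The nonTG means of Fabp4 (2.01) and Isoc2a (1.48) and the KDM1A TG mean of Gm17695 (1.65) lay under the filter level of 2.07, so the sizes of these 3 differences are as measured and bound the folds only from below, at 13.6, 2.12 and 2.71. The error of the means is not part of these bounds. Every KDM1A TG array lay on the same side of both nonTG arrays for these genes.

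Fabp4 and Car3 are abundant in adipocytes, so fat tissue carried along with the embryos may be a source of their RNA. A list of 22 other adipocyte markers was written before its values were seen, and the 11 tested had a median difference of 0.381 between KDM1A TG and nonTG, at the 97.48th percentile of 10000 random lists of like level, above the 95th percentile set in advance. That median rested on Scd1, Lpl and Cd36, which also belong to the lipid list whose result had been seen, and the 8 markers without them had a median of 0.178, at the 63.3rd percentile. Adipoq and Plin1, abundant in adipocytes, had differences of -0.12 (upper 95% limit 0.603) and -0.53 (upper limit 0.191), a comparison chosen afterwards. Slc2a4 was also below 0, at -0.71, and the other 8 markers lay above 0. Adipoq and Plin1 had mean levels of 2.67 and 3.07 in KDM1A TG, against array medians of 2.73 to 2.86. Their signal over background is unknown, so they do not exclude fat. Adipocyte RNA and a difference between the sires therefore cannot be told apart for these genes, and the latter was not tested.

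The 75 genes higher in KDM1A TG than in C57BL/6 embryos may reflect RNA of oviduct cells, array spread, the sire or chance. Their deviations within groups correlated with the oviduct marker mean at a median of 0.475, above 0 for 66 genes, at the 81.3rd percentile of matched random sets (0.0744 to 0.579), so that oviduct RNA and sire cannot be told apart for these genes. With the marker mean as a covariate their median change went from 1.41 (SE 0.334) to 1.07 (SE 0.401), 60 kept an unadjusted p under 0.05, and the prior degrees of freedom went from 73 to 23.5, so the calls ended with a smaller change, a larger error and a less certain spread, whose parts were not separated. After quantile normalization 902 genes instead of 1620 had an unadjusted p under 0.05, 71.6% of them higher against 85.2% before, the higher calls went from 75 to 4, the median change of the 75, picked for that change, was 1.21 (SE 0.334), and another split of the arrays reached 71.7%, so array spread cannot be told apart either. Of the 10 splits of the 6 arrays, 2 gave as many genes, with 83 in the real split and 423 in the highest other, and so few splits cannot give a share under 0.05.

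Among 56 splits of the 8 arrays into 5 and 3, 3 called at least as many genes as the 151 of the real split, so chance was not excluded for both kinds of sires against C57BL/6. The highest other split called 534 and set C57BL/6 replicates 1 and 3 with KDM1A TG replicate 2, the 3 arrays of lowest oviduct marker mean, against the rest, as did the split with 423. The next highest other split of the 8 arrays called 215. It set KDM1A TG replicates 1 and 3 with nonTG replicate 1, the 3 arrays of highest oviduct marker mean, against the rest. Whether a structure of the samples other than the sire lies behind these counts was not tested.

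Maternal oocyte genes were lower in nonTG than in C57BL/6 embryos by 0.647 relative to all genes (relative median -0.647). The shift was -0.72 after quantile normalization, in a test chosen after the results were seen. The interquartile ranges were 2.06 and 1.87 in the nonTG arrays and 1.91 to 2.02 in the C57BL/6 arrays. This scaling therefore had little difference in array spread to remove, and the shift did not depend on it. A smaller embryo share of the RNA where oviduct RNA is present may contribute. The shift was -0.0377 with the oviduct marker mean as a covariate (median SE 0.412 of its genes). The list means deviated within groups in opposite directions (r = -0.871). Within groups the oviduct marker mean also went with the interquartile range of the array (r = 0.834). The covariate therefore does not separate oviduct RNA from array spread. The same covariate took the maternal genes past 0 in KDM1A TG, to 0.317 (adjusted p = 0.000922, and adjusted p = 0.495 with an estimated correlation), and in both kinds together, to 0.175 (adjusted p = 0.0341, and adjusted p = 0.732 with an estimated correlation), which a smaller share alone does not predict, so that share and sire cannot be told apart for these genes. A later stage of the nonTG embryos is not settled, since the preimplantation lineage list gave an adjusted p of 0.4802, and a difference between the sires stays open and untested.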

How the results depend on the processing

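The oviduct marker mean as a covariate and the omission of KDM1A TG replicates 1 and 3 were chosen after seeing the data, and all other alternatives were planned. The omission left 1 KDM1A TG array, whose spread was taken from the other groups.

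Directions held more often than calls, but these genes and lists had been picked for their values in the same data. Where arrays of a gene did not overlap between groups, leaving out arrays could not turn its direction. Over the alternatives, values of called gene lists kept direction and call 626 times, lost the call 210 times and reversed 19 times. Values of named genes kept direction and status, passed or not passed, 4060 times, lost the call 369 times, gained it 170 times and reversed 13 times. Genes that passed in neither fit are among the 4060, so that number does not count calls that held. Counts of genes stayed within 1.5 times of the reported one 25 times and moved further 71 times, counts of lists 74 and 18 times, and the correlation between comparisons held within its spread 11 times and moved 3 times. Fabp4 and Car3 in KDM1A TG against nonTG embryos passed under each of the 20 alternatives run for single genes. No detection calls were used here, so the signal over background that limits low genes is unknown.

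For KDM1A TG against C57BL/6, 83 genes became 138 with no filter (124 higher and 14 lower), 53 with a filter at the 50th percentile, 128 with trend and robust variances, 1694 with array weights, 174 at an adjusted p under 0.1, 1620 at an unadjusted p under 0.05 with 1.5-fold and 15 with treat. Scaling gave 5 genes with quantile normalization, 5 with cyclic loess (4 higher and 1 lower each) and 151 with arrays centred on their median (142 higher and 9 lower), and testing all probesets gave 7. The covariate left 1 gene, and so did the omission of KDM1A TG replicates 1 and 3. For nonTG against C57BL/6, 15 became 44 with no filter, 9 at the 50th percentile, 30 with trend and robust variances, 47 with array weights, 6 with only the 2 groups in the fit, 42 at an adjusted p under 0.1, 941 unadjusted with 1.5-fold and 4 with treat. Quantile normalization left 1 and cyclic loess 1, both lower, the covariate 4 and the omission 6 (4 higher and 2 lower). Testing all 16072 probesets left 0 by limma, with 1273 at an unadjusted p under 0.05. The cause was not tested, apart from thresholds, filters and omissions that change the number of genes or arrays by construction.

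For KDM1A TG against nonTG, 5 genes became 2 at the 50th percentile filter, 2 with quantile normalization, 2 with cyclic loess, 2 with treat, 3 with array weights, 3 with the mean of a gene's probesets, 3 with the covariate, 3 with the omission, 9 with trend and robust variances and 733 unadjusted with 1.5-fold. For both kinds of sires against C57BL/6, 151 became 91 at the 50th percentile filter, 6 with quantile normalization, 1 with cyclic loess, 735 with array weights, 92 with the 3 groups kept apart in the fit, 14 over all probesets, 95 with the mean of probesets, 1461 unadjusted with 1.5-fold, 250 at an adjusted p under 0.1, 30 with treat, 4 with the covariate and 3 with the omission. The cause was not tested.

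With an estimated correlation 0 lists passed camera in each of the 4 comparisons, where 1, 0, 2 and 0 had an unadjusted p under 0.05. Fry called 2 lists for KDM1A TG against C57BL/6 and 0 in the other 3. Cyclic loess gave 6 lists for KDM1A TG against C57BL/6, the covariate 1 for nonTG against C57BL/6, and for KDM1A TG against nonTG quantile normalization gave 4, cyclic loess 2 and array weights 5. Of the 19 reversals of called lists, 13 came with the covariate, 3 with the omission, 2 without nonTG replicate 1 and 1 without KDM1A TG replicate 2. Some medians relative to all genes reversed, and the cause was not tested beyond the test of oviduct RNA on maternal genes. In KDM1A TG against C57BL/6 they became 0.3373 for 2-cell activation, 0.3167 for maternal and -0.1068 for stromal genes, and without KDM1A TG replicates 1 and 3 they were 0.2942, 0.2313 and, for oviduct markers, -0.03401. In nonTG against C57BL/6 the covariate gave 0.06302 for 2-cell activation, 0.2161 for cell cycle, 0.1501 for ribosome biogenesis, 0.02211 for histone and -0.2163 for stromal genes, and -0.03771 for maternal genes, whose camera direction turned. For both kinds together it gave 0.249, 0.1753, 0.2995 and -0.2609 for 2-cell activation, maternal, cell cycle and stromal genes. The 2-cell activation and maternal genes in KDM1A TG, and these and the cell cycle genes in both kinds together, then passed as higher with the preset correlation, and none did with an estimated one.

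Single named genes also changed sign. Xbp1 was at -0.007543 in KDM1A TG against C57BL/6 without KDM1A TG replicates 1 and 3. With the covariate, Gmnn (0.0194), H2bc12 (0.01539), Psmb6 (-0.1356), Pomp (-0.003673) and Mgp (-0.372) changed sign in nonTG against C57BL/6, and Gm2022 (0.05159), Omt2b (0.1267), Hspb1 (-0.08302), Psmb6 (-0.1002) and Mgp (-0.07118) for both kinds together. The cause was not tested.

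Leaving out each array in turn gave 9 to 254 genes and 5 to 12 lists for KDM1A TG against C57BL/6, 3 to 80 genes and 4 to 12 lists for nonTG against C57BL/6, 2 to 17 genes and 1 to 12 lists for KDM1A TG against nonTG, and 18 to 279 genes for both kinds together. The lowest counts of genes came without KDM1A TG replicate 3, nonTG replicate 2, KDM1A TG replicate 2 or 3, and KDM1A TG replicate 3. The highest counts also came with an array left out, so the total number of arrays alone does not set the count. Whether the loss of an array from a compared group lowered it was not tested. In nonTG against C57BL/6 the stromal median ran from -0.05553 to 1.073, Mgp from -0.01414 to 1.713 and H1f1 from -1.76 to 0.125, each turning without nonTG replicate 1, which left 1 nonTG array whose spread was taken from the other groups. The 2-cell activation median in KDM1A TG against nonTG ran from -0.2184 to 0.4689, and the correlation between the comparisons from 0.4764 to 0.7243, where simulated unchanged groups of the same arrays gave means of 0.353 to 0.548.

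Whether the replicate numbers pair the arrays was not settled. Deviations of same-numbered arrays correlated at -0.378 to 0.179, and not every array correlated best with its own number. Between KDM1A TG and nonTG the same-numbered arrays gave 0.1125 and 0.179. Deviations from a mean of 2 arrays mirror each other, so these values cannot decide. With the number as a block 23 genes passed for nonTG against C57BL/6 (6 higher and 17 lower), and 76, 4 and 122 passed for KDM1A TG against C57BL/6, KDM1A TG against nonTG and both kinds together.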

Other observations

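The genes of this part were chosen and the relations tested only after the results were seen.

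Mir365-1, the gene of a microRNA precursor, was lower in embryos of both kinds of sires from the transgenic line. Its log2 values were 5.90, 4.94 and 4.29 in the C57BL/6 arrays, 2.63, 2.24 and 3.27 in the KDM1A TG arrays and 3.26 and 2.10 in the nonTG arrays. It fell by 2.33 in KDM1A TG (adjusted p = 2.19e-05), by 2.36 in nonTG (SE 0.392, adjusted p = 0.000598) and by 2.34 in both together (adjusted p = 7.26e-09). It also passed in these 3 comparisons after quantile normalization, after cyclic loess, with the oviduct marker mean as a covariate and without KDM1A TG replicates 1 and 3, with changes of -2.35 to -2.91. A probeset for a precursor does not measure the mature microRNA.

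Retnla, which encodes a resistin-like protein of macrophages and epithelia, and Dcpp2, a demilune cell and parotid protein gene, stood highest in C57BL/6 replicate 2, at 6.78 and 5.12 on the log2 scale. Retnla was at 2.23 and 2.31 in the other C57BL/6 arrays and between 0.71 and 3.41 in the remaining 5. Dcpp2 also reached 4.78 in KDM1A TG replicate 3. With the oviduct marker mean as a covariate both passed as lower in nonTG than in C57BL/6 embryos (log2 changes of -4.36 and -3.02, adjusted p = 0.00722 and 0.0114). Without it neither did (-2.24 and -1.25, adjusted p = 0.0592 and 0.392). The nonTG mean of Retnla, 1.54, lay under the filter level, so the size of its change is not measured. C57BL/6 replicate 2 also had the highest oviduct mean of its group, 5.765, so 1 array may set both calls, which was not tested. The predicted gene Gm5166 was lower in nonTG both ways (-1.86 and -2.46 as measured, adjusted p = 0.008 and 0.00722), at least 1.89-fold without the covariate, with a nonTG mean of 1.12 under the filter level of 2.07.

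Of the 20 oviduct markers, Dynlrb2, a dynein light chain gene of ciliated cells, had mean log2 levels of 9.71 in C57BL/6, 9.85 in KDM1A TG and 10.16 in nonTG embryos. Ltf, lactoferrin, stood at 7.34, 8.24 and 8.42, Wfdc2 at 6.44, 7.53 and 7.83, and Lcn2, lipocalin, at 7.07, 7.10 and 7.41. Wt1 and Pax8 belong to another list too. How many of the 20 the embryo expresses itself is not known here, since no sample free of oviduct fluid was analysed.

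The mean of the oviduct markers was set against 4 other measures over the 8 arrays. With the maternal gene mean r was -0.769 (exact permutation p = 0.031, adjusted p = 0.0611) and rho was -0.548 (exact permutation p = 0.171, adjusted p = 0.171). With the 2-cell activation mean r was -0.708 (exact permutation p = 0.0526) and rho -0.619 (exact permutation p = 0.115). With the stromal and muscle mean r was 0.784 (exact permutation p = 0.0177) and rho 0.833 (exact permutation p = 0.0154). The interquartile range of the array gave an r of 0.68 (exact permutation p = 0.0611) and a rho of 0.643 (exact permutation p = 0.0962). No relation had an adjusted p under 0.05 (0.0611 for each r, and 0.0616 to 0.171 for rho). Without C57BL/6 replicates 1 and 3, the 2 arrays farthest from the median, r was -0.578, -0.58, 0.664 and 0.632. For deviations from the group means r was -0.871, -0.82, 0.709 and 0.834 in the same order.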
